A study of Homo sapiens with 12 samples.

How the data were processed

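The series measured where the glucocorticoid receptor (NR3C1) and STAT5B bound chromatin in SUPT-1 cells, by chromatin immunoprecipitation and sequencing (ChIP-seq). The labels listed 12 samples in 12 groups, of which 8 were ChIP libraries and 4 were input libraries. Each group held 1 library, so no value had a replicate and the spread between cultures was not measured. The input libraries were not analysed here on their own. The groups were set by antibody, STAT5B form (wild type or N642H) and treatment (none, or prednisolone at 250 µg per ml for 16 hours).

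Each ChIP library came as 1 list of peaks. BWA, MACS2 and deepTools were named in the submitters' processing notes, with the genome build hg38, and their versions were not given in the sources used here. From the values, peaks were called separately for each library, and the deposited lists held peaks with −log10 q of at least 2. For each peak the authors deposited its span, the offset of its summit, a score that was 10 times the −log10 q as a whole number, a fold enrichment (a ratio of ChIP pileup to local background), and −log10 p and −log10 q. No p-value or q-value was recomputed. These are the authors' own values for each peak, and they were used only to describe, rank and filter regions within a list.

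No peaks overlapped within a list, so each peak was 1 region. Regions on the numbered chromosomes, X and Y were used, and the others were counted separately. Coordinates are on hg38 and counted from 1. Gene names and spans came from an NCBI RefSeq table of GRCh38.p14 with 19355 protein-coding genes. Genes on alternative or unplaced sequences were left out. The table gave no strand, exons or sequence. Distances to transcription start sites, exon and intron classes, and the planned searches for STAT5 and glucocorticoid receptor motifs were therefore not analysed here. A region was instead called at a gene end when its summit lay within 1 kb of either end of a protein-coding gene.

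The depth of the libraries was recovered from the deposited values. The pileup and the local background at each summit were solved from the fold enrichment, with a pseudocount of 1, and from the −log10 p under the Poisson formula that MACS2 uses. All peaks of the 6 lists with more than 50 regions were solved. The genome background was the lowest level shared by at least 5 peaks, the fragment length was taken from the narrowest peak, and their quotient, divided by the size of 1 pileup step, gave ChIP tags per kb. That step was 0.894 for NR3C1 and 0.849 for STAT5B in the WT line with prednisolone, and 1 in the other 4 lists. On simulated peaks, with 400 regions per case, the pileup was recovered in 100% of regions. The untreated NR3C1 lists held too few peaks for this. Regions whose local background was at least 10 times the genome background of their library are called high-background regions.

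Lists were compared by overlap of at least 1 bp. Shares have exact Clopper-Pearson 95% intervals, which cover counting error over the regions of these libraries only. Chance overlap was estimated from 1000 random placements of the regions on their own chromosomes between the first and the last annotated gene, because assembly gaps were not known, and from shifts of 5 kb to either side. Two-sided Fisher's exact tests compared groups of regions, and 19 such tests were adjusted together by the Benjamini-Hochberg method. They compare regions of these libraries, not conditions. Mantel-Haenszel odds ratios were computed within 5 groups of equal size by pileup. On simulated lists the planted overlap was found exactly in 20 of 20 runs, and the interval covered the true odds ratio in 18 of 20.

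A gene was linked to a list when a summit lay in its span or within 20 kb. For 10 gene lists fixed before the data were examined, the number of linked genes was set against 10000 random lists of protein-coding genes of the same size, matched on gene-span decile. Percentiles describe 1 library each and are not tests. In a check on NR3C1 regions of the N642H line, 1.5% of 200 random lists of 30 genes passed the upper percentile limit, as did 100% of 50 lists with 15 planted linked genes. The genes named in the text followed a rule set in advance. It took 14 genes in every library, with or without a region, the nearest gene of the 10 strongest regions of each list, up to 6 linked members of each gene list, and the nearest genes of the 10 strongest STAT5B regions with prednisolone in both lines that either lay at NR3C1 regions of both lines or were in neither untreated list. The rule named the nearest transcription start site, for which the nearest gene span stood in here. Some genes that the rule names are not reported here. Genes outside this rule are said to have been chosen after their values were seen. SOCS1 and BCL6 were followed through all libraries as additions of that kind.

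The alternatives set in advance were another overlap rule, −log10 q of at least 5, fold of at least 5, equal list lengths, removal of regions found in an untreated NR3C1 list, all sequences, and another solution for the background. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.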

Results

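NR3C1 and STAT5B binding was mapped in SUPT-1, an established human T-cell acute lymphoblastic leukaemia line. The cells were made to overexpress either wild-type STAT5B (WT line) or the activating mutant N642H (N642H line). Cells were left untreated or given prednisolone, a synthetic glucocorticoid that is a ligand of NR3C1. The study's title places the comparison in the setting of steroid resistance and of BCL2 and BCLXL, the protein of BCL2L1. There were 8 ChIP libraries, 1 for each antibody, line and treatment, so differences between libraries have no replicate check. Folds and −log10 q values are the authors' own for each peak. Where values of different lists stand side by side they describe each list and do not measure a change.

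The 8 lists held between 2 and 4542 regions. NR3C1 had 2 regions in each untreated line, 995 in the WT line with prednisolone and 2888 in the N642H line with prednisolone. STAT5B had 2267 regions in untreated WT cells and 4542 in untreated N642H cells. With prednisolone these numbers were 766 and 446. Recovered ChIP depth was 7.55 and 4.79 tags per kb for NR3C1 with prednisolone in the WT and N642H lines. For STAT5B it was 8.31 and 7.95 tags per kb in the WT line without and with prednisolone, and 6.26 and 4.14 tags per kb in the N642H line. With the most frequent background in place of the lowest, these 6 depths lay between 9.90 and 15.1 tags per kb and in another order. The narrowest peaks were between 75 and 82 bp in 4 of these libraries, and 137 bp (NR3C1) and 156 bp (untreated STAT5B) in the N642H line, so the libraries also differed in fragment length. High-background regions made up 68 of the 446 STAT5B regions of the N642H line with prednisolone (15.2%), 58 of its 2888 NR3C1 regions, and at most 6 regions in any other of the 6 long lists.

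**Figure D1:**
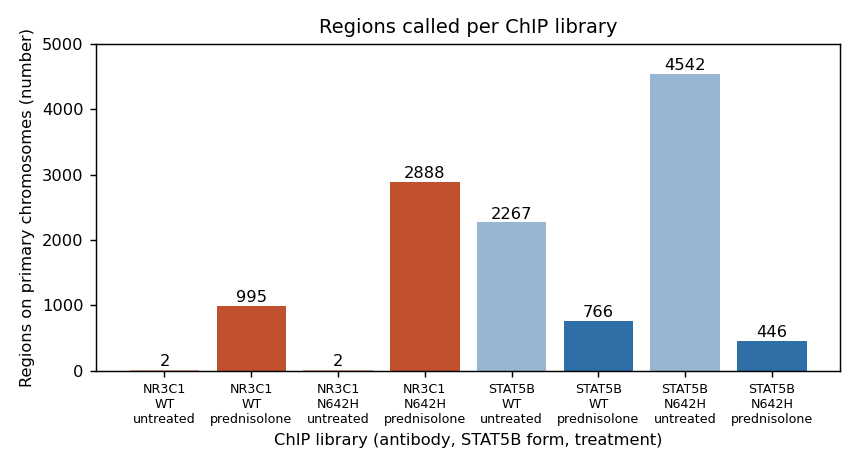
Number of regions on primary chromosomes (vertical axis) in each of the 8 ChIP libraries, coloured by antibody, with untreated libraries in the paler shade. NR3C1 went from 2 regions without prednisolone to 995 (WT) and 2888 (N642H) with it, while STAT5B went from 2267 to 766 and from 4542 to 446.

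The first comparison asked where NR3C1 bound with prednisolone and whether the 2 lines differed. Without prednisolone only the ends of PGAM1, a glycolytic enzyme gene, and COX17, a copper chaperone gene, carried NR3C1 regions, and both regions recurred in all 4 NR3C1 lists. With prednisolone the strongest regions of the WT line lay in KLF13 (fold 76.9, −log10 q 250) and FKBP5 (fold 73.0, −log10 q 244). FKBP5 encodes a co-chaperone of the receptor and is a classical glucocorticoid target. The next lay 109424 bp from BTG1, an antiproliferative gene, and 41456 bp from TOB1. In the N642H line the strongest regions were near SMOX (fold 118, −log10 q 494), in KLF13 (fold 114, −log10 q 493), 30017 bp from SOCS1 (fold 95.5, −log10 q 460) and in FKBP5 (fold 106, −log10 q 453). The 10 strongest regions of each line were all called in the other line as well. They also included sites near KLF9, CCND3, HTR5A and ANAPC16, and a site 90811 bp from ZFP36L2. Another lay 166695 bp from NR3C1 itself (chromosome 5, 143601948 to 143602448).

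Of the WT regions, 895 of 995 (89.9%, 95% interval 87.9 to 91.7) overlapped an N642H region. Of the N642H regions, 887 of 2888 (30.7%, 29.0 to 32.4) overlapped a WT region, and 2001 did not. Random placement gave a mean of less than 1 overlapping region in either direction. When both lists had the same length, 63.1% of WT and 62.3% of N642H regions were shared.

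Glucocorticoid response genes were linked to NR3C1 regions in both lines. The WT list had 19 of 30 members linked and the N642H list 20 of 30, each more than in any of 10000 random lists (random medians 1 and 3). Examples were FKBP5, KLF9, ZFP36L2, CXCR4, a chemokine receptor gene, DUSP1, a MAP kinase phosphatase gene, and ZBTB16 (−log10 q 71.6 in WT and 164 in N642H). At TSC22D3, which encodes the glucocorticoid-induced leucine zipper, the strongest region lay 38996 bp from the gene in the WT line (fold 73.8) and 39001 bp from it in the N642H line (fold 106). The gene nearest to that region was PRPS1, 23199 bp away in the WT line. PER1, another common glucocorticoid target, had no NR3C1 region within 50 kb in any list. STAT5 targets had 4 of 30 members linked in the WT line (98.32 percentile) and 14 of 30 in the N642H line (more than any random list). CCND3, SOCS1, BCL6 and BCL2L1 were linked in both lines. PIM1, a survival kinase gene (fold 19.6), SOCS2 (fold 13.7), CISH (fold 7.78) and BCL2 (fold 18.4) were linked in the N642H line and had no NR3C1 region within 50 kb in the WT line. The difference in list counts between lines was not tested, and the N642H list was the longer one. Genes of steroid handling (2 of 15 in each line), non-blood tissues (0 of 16 in each) and other blood cell types (0 and 1 of 16) did not stand above the random lists, nor did highly expressed promoters (1 and 3 of 24).

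The BCL2 family was linked at 2 of 20 members in the WT line (83.39 percentile) and 7 of 20 in the N642H line (99.79 percentile). BCL2L1, which encodes the anti-apoptotic protein BCLXL (gene ID 598, chromosome 20, 31664452 to 31723963), carried a strong NR3C1 region inside the gene in the N642H line only, at 31675720 to 31676298 (fold 41.7, −log10 q 158). A weaker region at 31708451 to 31708562 was present in the WT line (fold 7.27), and one overlapping it in the N642H line (fold 5.52). BCL2 (gene ID 596, chromosome 18, 63123346 to 63320090) had 5 NR3C1 regions in the gene or within 50 kb in the N642H line and none in the WT line. The strongest, at 63290920 to 63291261, had a fold of 18.4. BCL2L11, which encodes the pro-apoptotic protein BIM and is a known glucocorticoid target in lymphoid cells, had overlapping internal regions in both lines, with fold 10.5 in WT (111157375 to 111157606 on chromosome 2) and 26.4 in N642H.

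**Figure D2:**
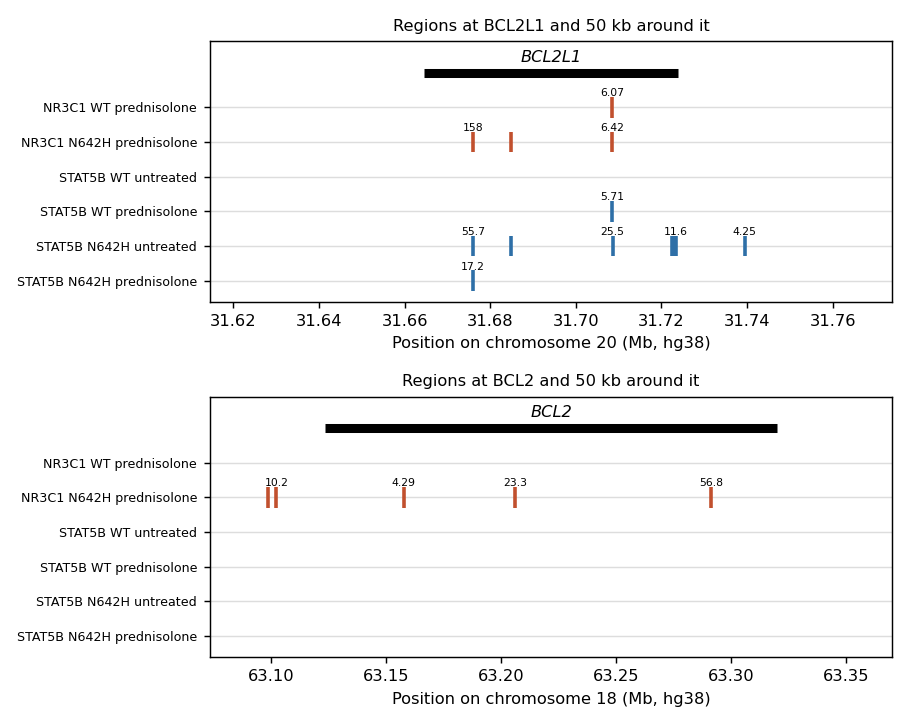
Maps of BCL2L1 (top) and BCL2 (bottom) with 50 kb to either side, on hg38 in Mb. Each tick is a region of the list named at the left, NR3C1 in orange and STAT5B in blue, with its −log10 q above it unless a stronger region lies within 10 kb, and the black bar is the gene. The BCL2L1 site at 31675720 to 31676298 was called only in N642H lists (158 for NR3C1, 55.7 and 17.2 for STAT5B), and BCL2 had regions only in the N642H NR3C1 list.

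The second comparison asked how STAT5B binding differed between the untreated WT and N642H lines. The labels name a STAT5B pull-down in each line and do not give the amount of either form. In the N642H line the strongest STAT5B regions lay in ARID3B (fold 33.3, −log10 q 99.3), 21126 bp from SOCS1 (fold 32.9, −log10 q 97.8), 28915 bp from GRAPL (fold 15.9, −log10 q 72.3), 8354 bp from DAD1 (fold 19.5, −log10 q 67.8) and 7925 bp from PIM1 (fold 25.8, −log10 q 67.3). The next included regions 45670 bp from RPS6KA1 (fold 23.8), in OTUD5 beside PIM2 (fold 27.3) and in BCL2L1 (fold 17.1, −log10 q 55.7). SOCS1, PIM1 and PIM2 are cytokine-induced genes downstream of STAT5. In the WT line the strongest regions were 28910 bp from GRAPL (fold 12.3, −log10 q 39.5) and near DAD1, and then at the ends of KMT2A, RPS7 and DRAP1 and 2249 bp from ZBTB7B. The PIM1, PIM2 and BCL2L1 sites had no STAT5B region in the WT line, and the SOCS1 site had one of fold 6.16. All 10 strongest WT regions were also called in the N642H line.

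Of the WT regions, 1392 of 2267 (61.4%, 59.4 to 63.4) overlapped an N642H region. In the other direction 1352 of 4542 N642H regions (29.8%, 28.4 to 31.1) overlapped a WT region. Random placement gave means below 2 regions. STAT5 targets were linked at 9 of 30 members in WT (96.14 percentile) and 17 of 30 in N642H (99.83 percentile). CISH and SOCS2, feedback inhibitors of cytokine signalling, had STAT5B regions in N642H (fold 12.7 and 9.61) and none within 50 kb in WT. BCL6, a transcriptional repressor gene, had one of fold 18.7 in N642H and 4.14 in WT, and MYC had one of fold 6.99 in N642H and 4.94 in WT. The IL7R and JAK-STAT pathway had 7 of 20 members linked in WT (97.09 percentile) and 14 of 20 in N642H (99.96 percentile), IL7R itself only in N642H. Highly expressed promoters, a list meant to show ChIP background, were also linked often, at 8 of 24 in WT (96.63 percentile) and 17 of 24 in N642H (99.99 percentile). UBB was among them in both lines. The BCL2 family (3 and 8 of 20), steroid handling genes (3 and 4 of 15), other blood cell types (1 and 4 of 16) and non-blood tissues (1 of 16 in each) did not stand above the random lists. BCL2 had no STAT5B region within 50 kb in any library.

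The third comparison asked what happened to STAT5B binding with prednisolone. In the WT line 450 of 2267 untreated regions (19.9%, 18.2 to 21.6) were also called with prednisolone, and 454 of the 766 prednisolone regions (59.3%, 55.7 to 62.8) were also called without it. In the N642H line 312 of 4542 untreated regions (6.87%, 6.15 to 7.64) were called with prednisolone, and 314 of 446 prednisolone regions (70.4%, 65.9 to 74.6) without it. With lists of equal length these shares were 38.1% and 38.9% in WT and 31.2% and 31.4% in N642H. In N642H cells the fold at the BCL2L1 site was 17.1 without and 12.9 with prednisolone, and at the PIM1 site 25.8 and 4.69. CISH and SOCS2 still had STAT5B regions there with prednisolone (fold 7.91 and 6.66), and IL7R had one at a site where no untreated STAT5B region lay (35854509 to 35854610 on chromosome 5, fold 6.76). In the WT line MYC had a region of fold 5.43 that did not overlap its untreated region, and BCL2L1, with none untreated, had one at 31708450 to 31708544 (fold 7.07). STAT5 targets were linked at 5 of 30 members in WT (96.73 percentile) and 7 of 30 in N642H (99.98 percentile) with prednisolone. In the N642H line 7 of the 10 strongest prednisolone regions by −log10 q were high-background regions on chromosomes 16, 5 and 4 with folds from 2.98 to 4.11. The others included regions 30007 bp from SOCS1 (fold 18.5) and in KLF13 (fold 15.6).

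STAT5B regions that coincided with an NR3C1 region were called again with prednisolone more often than those that did not. In the WT line 88 of 163 untreated STAT5B regions at an NR3C1 region (54.0%, 46.0 to 61.8) were called again, against 362 of 2104 others (17.2%, 15.6 to 18.9), with an odds ratio of 5.65 (Fisher's exact test, adjusted p = 1.29e-23). In the N642H line the shares were 158 of 805 (19.6%, 16.9 to 22.5) and 154 of 3737 (4.12%, 3.51 to 4.81), with an odds ratio of 5.68 (Fisher's exact test, adjusted p = 7.20e-43). With lists of equal length the odds ratio was 5.26 in WT (Fisher's exact test, adjusted p = 8.57e-12) and 2.53 in N642H (Fisher's exact test, adjusted p = 2.23e-05). Within groups of equal untreated pileup the odds ratio was 3.46 (2.38 to 5.04) in WT and 2.50 (1.93 to 3.24) in N642H. This comparison was chosen after the lists had been seen. The control depth recovered from the background was 6.75 tags per kb for both prednisolone lists of the WT line. For both of the N642H line it was 10.6 tags per kb. The NR3C1 and STAT5B lists of a line may thus share a control, and noise in it could raise their overlap here and below. This was not tested.

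**Figure D3:**
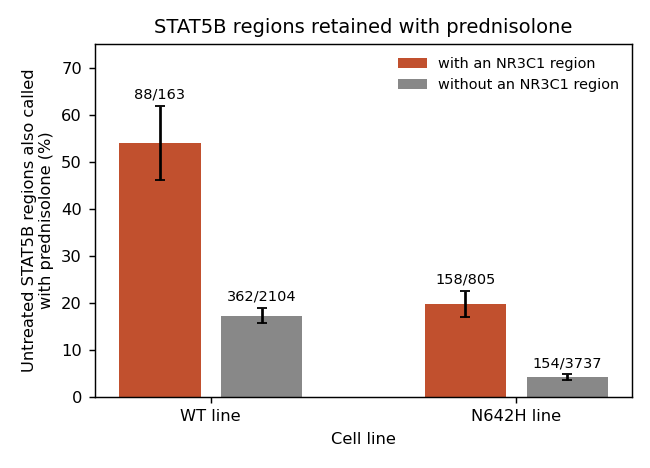
Share of untreated STAT5B regions that were also called with prednisolone (vertical axis, %), split by overlap with an NR3C1 region of the same line. Bars give the share, whiskers the exact 95% interval, and the fractions the regions counted; the share was higher at NR3C1 regions in both lines (54.0% against 17.2% in WT, 19.6% against 4.12% in N642H).

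The fourth comparison asked how far STAT5B and NR3C1 occupied the same sites in prednisolone-treated cells. In the WT line 141 of 766 STAT5B regions (18.4%, 15.7 to 21.3) overlapped an NR3C1 region, and in the N642H line 239 of 446 (53.6%, 48.8 to 58.3). Without high-background regions the N642H share was 48.9% (43.8 to 54.1) of 378 regions. The NR3C1 list of the N642H line was much the longer. With STAT5B and NR3C1 lists cut to equal length within each line, the shares were 13.6% (11.2 to 16.2) in WT and 14.1% (11 to 17.7) in N642H. These lists held 766 regions in WT and 446 in N642H, so NR3C1 list length still differed between lines. Random placement gave means below 1 region, and shifting the regions by 5 kb gave 0.50 in WT and 10.5 in N642H. The untreated STAT5B regions lay at these same NR3C1 regions in 163 of 2267 cases (7.19%) in WT and 805 of 4542 (17.7%) in N642H. The untreated lists were longer, and when they held only as many of their strongest regions as the prednisolone list, the shares were 88 of 766 (11.5%, 9.32 to 14.0) in WT and 226 of 446 (50.7%, 45.9 to 55.4) in N642H, a comparison chosen after the lists had been seen. Of the STAT5B regions of the WT line with prednisolone, 45 were shared with the N642H line and lay at NR3C1 regions of both lines. The strongest of these were in FKBP5 (STAT5B fold 17.2 in WT and 11.2 in N642H), near GRAPL, in ARID3B, and in KLF13 (14.5 and 15.6). Further sites were near DAD1, RTTN and EAPP, at KMT2A, and 109440 bp from BTG1 and 537131 bp from GSDMC. By STAT5B strength in N642H they also included sites in KIF3C and near RPS6KA1 and HTR5A.

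A set of 13 STAT5B regions was called with prednisolone in both lines and in neither untreated list, and 10 (WT) and 12 (N642H) of them lay at NR3C1 regions. The 13 included sites 109440 bp from BTG1 (STAT5B fold 14.4 in WT and 8.52 in N642H), 90815 bp from ZFP36L2, in KIF3C and in SPEF2. Others lay 166736 bp from NR3C1 (fold 10.2 and 10.6), near CXCR4 (fold 9.46 and 9.17) and near TOB1. A site lay in IKZF1 (fold 8.79 and 8.61), which encodes the lymphoid transcription factor Ikaros. Further sites were in PRKAB2, near HTR5A, and near PRPS1 at the site given above for TSC22D3. Glucocorticoid response genes were linked to STAT5B regions at 7 of 30 members in WT (99.86 percentile) and 8 of 30 in N642H (more than any random list) with prednisolone, against 9 of 30 (95.80 percentile) and 18 of 30 (99.98 percentile) without it.

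STAT5B regions absent without prednisolone were not shown to lie at NR3C1 regions more often than those present without it. In WT the shares were 53 of 312 (17.0%) and 88 of 454 (19.4%; Fisher's exact test, adjusted p = 0.473). In N642H they were 81 of 132 (61.4%) and 158 of 314 (50.3%; Fisher's exact test, adjusted p = 0.0548). Without high-background regions the N642H order turned, to 28 of 65 (43.1%) and 157 of 313 (50.2%; Fisher's exact test, adjusted p = 0.404). The N642H call depended on the setting. By Fisher's exact test the adjusted p was 0.000669 within 500 bp, 0.0232 with −log10 q of at least 5 and 0.0472 on all sequences. Each of these had the higher share in absent regions. With lists of equal length it was 0.000403 in the opposite direction (Fisher's exact test). Absent then meant only outside the 446 strongest untreated regions, which is another class of regions.

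Where the regions lay also separated both factors. Gene ends held 57.1% of untreated STAT5B regions in WT (55.0 to 59.1) and 55.5% in N642H (54.0 to 56.9), against 2.38 to 3.34% of random positions across the 6 lists. With prednisolone the STAT5B shares were 58.6% in WT (Fisher's exact test against untreated, adjusted p = 0.473) and 46.4% in N642H (Fisher's exact test, adjusted p = 0.000466), and the N642H share was 54.8% without high-background regions. NR3C1 regions lay at gene ends in 9.45% of cases in WT and 11.8% in N642H, and inside genes away from their ends in 45.2% and 45.5%. Random positions lay inside genes, ends included, in 42.6% (WT) and 43.3% (N642H) of cases. In a comparison chosen after the lists had been seen, STAT5B regions with prednisolone that overlapped NR3C1 lay at gene ends less often than the others, in 33 of 141 against 416 of 625 cases in WT (23.4% and 66.6%, Fisher's exact test, adjusted p = 1.81e-20) and 70 of 239 against 137 of 207 in N642H (29.3% and 66.2%, Fisher's exact test, adjusted p = 1.30e-14).

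NR3C1 regions of the N642H line were then compared by whether untreated STAT5B lay there, a comparison chosen after the lists had been seen. Of the NR3C1 regions without a WT call, 592 of 2001 (29.6%) overlapped an untreated N642H STAT5B region, against 211 of 887 with one (23.8%; odds ratio 1.35, Fisher's exact test, adjusted p = 0.00219). At equal NR3C1 pileup the odds ratio of a WT call at such STAT5B regions was 0.823 (0.669 to 1.01), an interval that included 1. NR3C1 regions at STAT5B regions called in N642H alone were called in WT in 84 of 446 cases (18.8%, 15.3 to 22.8). The share was 656 of 2010 (32.6%, 30.6 to 34.7) where no STAT5B region was called, and 127 of 357 (35.6%, 30.6 to 40.8) where STAT5B was called in both lines. NR3C1 regions at STAT5B regions of the WT line alone numbered 75, of which 20 (26.7%, 17.1 to 38.1) were called in WT. Within groups of equal NR3C1 pileup, the odds ratio of a WT call against regions without STAT5B was 0.453 (0.342 to 0.600) for STAT5B in N642H alone, 1.68 (1.26 to 2.24) for STAT5B in both lines, which was 1.63 (0.968 to 2.76) with lists of equal length, and 1.12 (0.593 to 2.11) for STAT5B in WT alone. For STAT5B in N642H alone it was 0.223 (0.140 to 0.356) with lists of equal length. The strongest NR3C1 regions without a WT call at a STAT5B region of the N642H line alone were near FRG1, in BCL2L1, 783161 bp from CCDC179, near ACTR3 and HLF, in TAGAP and near RIN1. Among all NR3C1 regions without a WT call, the one near FRG1 ranked 9 by −log10 q. Those above it, such as regions in DLEU7 (fold 82.4) and near NF2 (fold 80.3), had no untreated STAT5B region in either line. These genes other than BCL2L1 fall outside the naming rule and were chosen after their values were seen.

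**Figure D4:**
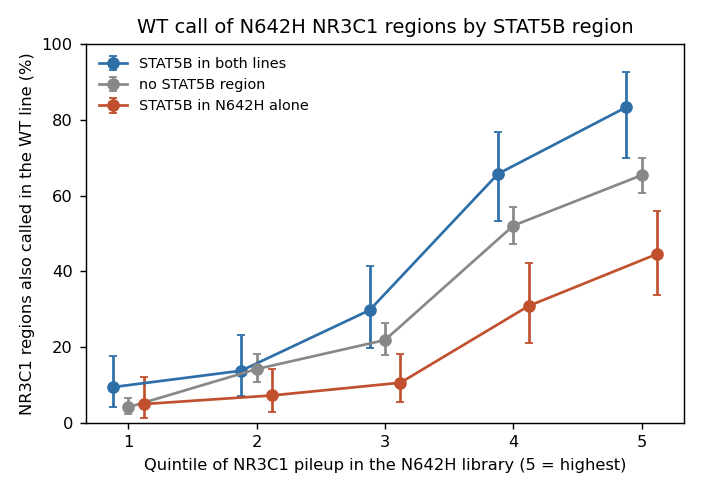
Share of N642H NR3C1 regions that were also called in the WT line (vertical axis, %), by quintile of their N642H pileup (horizontal axis) and by where untreated STAT5B was called, leaving out the 75 regions with STAT5B in WT alone. Points give the share and whiskers the exact 95% interval; in the highest quintile the shares were 83.3% for STAT5B in both lines, 65.4% for no STAT5B region and 44.6% for STAT5B in N642H alone.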

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

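The tests of a difference between lines, their repeats with lists of equal length or without high-background regions, and the exact McNemar tests were chosen after the results had been seen. All of these tests compare regions of single libraries, not conditions.

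Regions on sequences outside the numbered chromosomes, X and Y entered no comparison. There were 11 for NR3C1 in the WT line and 34 in the N642H line with prednisolone, 11 and 7 for STAT5B in the WT line without and with prednisolone, and 15 and 32 in the N642H line.

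The share of STAT5B regions at gene ends moved differently with prednisolone in each line, from 57.1 to 58.6% in WT and from 55.5 to 46.4% in N642H, with a ratio of odds ratios of 0.653 (0.505 to 0.844). Without high-background regions the ratio was 0.90 (0.688 to 1.18), and with lists of equal length 1.25 (0.898 to 1.75).

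The share of STAT5B regions at an NR3C1 region of the same line went from 7.19 to 18.4% in WT and from 17.7 to 53.6% in N642H, with a ratio of odds ratios of 1.84 (1.34 to 2.52), and of 1.53 (1.11 to 2.12) without high-background regions. With the longer untreated lists held to the length of the prednisolone lists, the shares went from 11.5 to 18.4% in WT and from 50.7 to 53.6% in N642H, and the ratio turned to 0.647 (0.438 to 0.955), so the larger rise in N642H depended on list length. Tags of the NR3C1 library in the STAT5B library, which would give STAT5B a fixed share of the NR3C1 pileup, stay open in both lines: over the 100 strongest NR3C1 regions without untreated STAT5B, a deviance as large as observed (135 in each) came up in 0.0045 (WT) and 0.001 (N642H) of 2000 simulations, but these held counting error alone (medians 95.2 and 90). Chromatin that gives signal with any antibody, if alike in both treatments, would give as many STAT5B calls without prednisolone. In WT 35 of the 100 strongest NR3C1 regions were called with prednisolone and 12 without (exact McNemar p = 2.38e-07). In N642H the counts were 27 and 22 (exact McNemar p = 0.458), or 27 and 7 with STAT5B lists of equal length (exact McNemar p = 3.59e-05). Chromatin alike in both treatments is thus argued against in WT. In N642H it was not decided, because equal length counted weaker untreated calls as absent. Although 0 of these 100 regions were called for NR3C1 without prednisolone in either line, the depth of those libraries was not recovered. Chromatin that gives such signal only with prednisolone was not tested, so this explanation stays open in both lines. Beside NR3C1 tags and such chromatin, a candidate explanation for WT is binding of STAT5B beside or through the ligand-bound receptor. It was not tested directly and rests on 1 library per group.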

How the results depend on the processing

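Region counts, shared regions, odds ratios, ratios of odds ratios, gene ends, gene lists, named genes and depths were recomputed, each under the alternatives that apply to it, with fold of at least 5 for region counts alone. The exact McNemar tests were repeated with equal lengths alone, and the fixed-share tests and the predicted calls under none. Alternatives without high-background regions, with gene ends within 5 kb, with the nearest gene span and with 50 kb around genes, and all those of stratified odds ratios, ratios between lines and the WT call of NR3C1 regions, were chosen after the data had been seen. With equal list lengths 63.1% of WT and 62.3% of N642H NR3C1 regions were shared, 43.7% and 42.2% of untreated WT and N642H STAT5B regions, 38.1% and 38.9% of untreated and prednisolone STAT5B regions in WT, and 31.2% and 31.4% in N642H. STAT5B regions with prednisolone at NR3C1 regions then made up 13.6% (WT) and 14.1% (N642H), and NR3C1 regions at STAT5B regions 13.2% (N642H), as only the strongest NR3C1 regions entered. Within 500 bp, 67.9% and 33.3% of untreated WT and N642H STAT5B regions were shared, and 23.4% and 66.6% of untreated and prednisolone regions in WT. With −log10 q of at least 5, the shares were 92.4% for WT NR3C1 regions in N642H, 22.9% for untreated N642H STAT5B regions in WT, 54.5% for WT prednisolone regions without it, 5.61% and 62.8% for N642H untreated and prednisolone regions, 60.2% for N642H STAT5B at NR3C1, and 10.5% (WT) and 6.64% (N642H) for NR3C1 at STAT5B. With summits within 200 bp, 48.4% of N642H STAT5B regions lay at NR3C1. Without high-background regions, 82.8% of N642H prednisolone STAT5B regions were also called untreated, and 6.36% of NR3C1 regions lay at STAT5B. The odds ratio of NR3C1 overlap for STAT5B regions absent against present without prednisolone was unstable. In WT it turned to 1.21 with −log10 q of at least 5. In N642H it was 2.21 within 500 bp, 1.83 with −log10 q of at least 5 and 1.54 on all sequences. There it was 0.752 without high-background regions, and 0.461 with equal lengths, where absent meant only outside the strongest untreated regions. The higher share called again at NR3C1 regions kept its direction and its side of the threshold under each alternative run, with odds ratios from 4.33 to 5.67 in WT and from 2.53 (equal lengths) to 6.39 in N642H, and also at equal pileup (2.65 to 3.5 in WT, 1.66 to 2.69 in N642H). So did the odds ratio of 1.35 for STAT5B at NR3C1 regions without a WT call (1.34 to 1.74) and that of 0.453 (0.223 to 0.461). The 0.823 became 0.776 with summits within 200 bp, 0.686 with −log10 q of at least 5, 0.534 with equal lengths and 0.735 without high-background regions, each with an interval below 1, and the 1.68 became 1.63 with equal lengths, its interval reaching 1. The ratios between lines turned with equal lengths, to 0.647 at NR3C1 regions and 1.25 at gene ends, and that at gene ends was 0.90 without high-background regions. With −log10 q of at least 5, WT STAT5B had 1254 untreated and 495 prednisolone regions, and gene ends held 10.5% of N642H NR3C1 and 54.0% of untreated N642H STAT5B regions. Gene ends within 5 kb held 19.9% and 22.0% of NR3C1 regions in WT and N642H, 65.9% and 67.0% of WT STAT5B regions without and with prednisolone, and 65.7% and 52.2% in N642H. With the most frequent background, depth was 13.6 (WT) and 9.90 (N642H) tags per kb for NR3C1, 15.1 for prednisolone STAT5B in WT, and 11.8 (untreated) and 10.4 (prednisolone) for N642H STAT5B. Beyond the removals named, the cause was not tested. Of the gene list counts 35 moved beyond 1.5 times and 145 did not, and of the named gene links 21 moved and 231 did not. Counting peaks in place of regions changed nothing, since no peaks overlapped. The motif alternatives, the removal of repeat sequence and the distances to transcription start sites were not run. No paired analysis was possible because the groups shared only 1 replicate number; taking the lines as blocks was not run. Among the 6 libraries with a recovered depth, that of STAT5B in N642H with prednisolone was lowest with the lowest background, at 4.14 tags per kb, and NR3C1 in N642H was lowest with the most frequent one, so depth limits what a missing call means in both.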

Other observations

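The tests of NR3C1 regions at STAT5B regions of the N642H line alone, and of STAT5B tags in the NR3C1 library, were chosen after the results had been seen.

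T-cell genes were also linked to NR3C1 regions. Of the T-cell and T-ALL regulators, 6 of 25 were linked in WT (99.87 percentile) and 15 of 25 in N642H (more than any of 10000 random lists). The strongest were in IKZF1 (fold 34.0 in WT and 92.5 in N642H), with others near TOX (9.79 and 50.8) and in NOTCH3 (7.55 and 12.5), a NOTCH receptor gene. T-cell surface and receptor genes were linked at 7 of 22 and 13 of 22, each more than in any random list, although WT had 4 of 22 (99.76 percentile) with −log10 q of at least 5. There were regions near CD7 (fold 27.3 and 58.8), CD69 (29.4 and 22.8) and the recombinase gene RAG2 (10.5 and 23.1). The IL7R and JAK-STAT pathway was linked at 7 of 20 (more than any random list) and 10 of 20 (99.99 percentile), with regions near IL7R (fold 14.9 and 53.8), in PIK3R1 (13.9 and 44.4) and in JAK1 (8.68 and 17.5). STAT5B itself carried an NR3C1 region in both lines (fold 20.5 in each, 42279847 to 42280062 on chromosome 17 in WT). STAT5A was linked through that same region. In N642H, CD3D and CD3G also shared a region (fold 6.47). Random lists were not matched for such neighbouring genes, which could raise the percentiles.

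STAT5B regions were linked to T-cell and T-ALL regulators at 10 of 25 in untreated WT (99.57 percentile) and 13 of 25 in untreated N642H (98.82 percentile), NOTCH3 being the strongest in both, and at 5 of 25 (98.46 percentile) and 2 of 25 (82.66 percentile) with prednisolone. T-cell surface genes were linked at 4 and 8 of 22 untreated and 1 and 0 of 22 with prednisolone, and did not stand above the random lists. With prednisolone, the IL7R and JAK-STAT pathway had 2 (WT) and 3 (N642H, 97.68 percentile) of 20 linked, and the BCL2 family 2 and 1 of 20. Steroid handling genes then had 0 and 1 of 15, other blood cell types 0 and 1 of 16, non-blood tissues 0 of 16 in both, and highly expressed promoters 2 of 24 in both.

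STAT5B had fewer regions with prednisolone in both lines. Lower depth was tested on untreated regions predicted to stay callable: in WT 408 of 1816 were called with prednisolone (22.5%, 20.6 to 24.5), where counting noise alone gave 77.6%, and in N642H 156 of 538 (29.0%, 25.2 to 33.0), where it gave 73.6%, so the 90% limit set beforehand was too high but the shares lay far below either. These predictions rest on pileups chosen for being high and so overstate the calls, and in N642H depth could still account for much of the fall, since 1282 of 4542 calls were predicted and 312 were made. An even loss of enrichment alone was not decided by the odds ratios of 3.46 (WT) and 2.50 (N642H) for a call at NR3C1 regions of equal pileup. Quintiles of a single untreated pileup do not equalise enrichment, and calls also met in another list are less often noise. An even loss could therefore give odds ratios above 1 as well. NR3C1 tags in the STAT5B library, left open above, would also raise them. A poorer precipitation in single libraries and an effect of prednisolone on STAT5B binding both stay open, as each group held 1 library.

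Many NR3C1 regions of the N642H line that coincided with untreated STAT5B lacked a WT call. Over all of them, lower sensitivity of the WT library stays open, with an odds ratio of a WT call of 0.823 (0.669 to 1.01) at equal NR3C1 pileup and 0.802 (0.65 to 0.990) at equal pileup and gene end position; the first was 0.776, 0.686, 0.534 and 0.735, with intervals below 1, under 4 alternatives (summits within 200 bp, −log10 q of at least 5, equal lengths, no high-background regions) and included 1 under the other 3. Where STAT5B was called in N642H alone, the odds ratio against regions without STAT5B was 0.453 (0.342 to 0.600). An even loss of sensitivity would not give this at equal enrichment. Quintiles of a single NR3C1 pileup do not equalise enrichment, and STAT5B tags could raise that pileup. Lower sensitivity was therefore not excluded here either. STAT5B tags in the NR3C1 library stay open. NR3C1 pileup per background was at least 3 times that of the higher STAT5B library at 24 of 592 (4.05%) of the regions without a WT call. The same held at 22 of 362 (6.08%) of those at STAT5B of N642H alone. Smaller ratios were not read either way because the regions were chosen for an NR3C1 call, which raises the ratio. At the BCL2L1 site, which was picked for its strength, the ratio was 2.74. Beside lower sensitivity and STAT5B tags, a hypothesis is that N642H STAT5B may favour receptor binding at sites such as BCL2L1. It was found and tested on the same single libraries, and a site open to both factors in N642H cells alone would give the same pattern. A further comparison, also chosen after the lists had been seen, split STAT5B regions by a WT STAT5B call and so asked another question. Untreated N642H STAT5B regions absent from the WT list lay at N642H NR3C1 regions in 438 of 3190 cases (13.7%). Those present in the WT list did so in 367 of 1352 (27.1%, odds ratio 0.427, Fisher's exact test, adjusted p = 2.88e-25). This was not compared at equal pileup.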
